A study of Mus musculus with 4 samples.

How the data were processed

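Epidermal keratinocytes of newborn mice were profiled by RNA sequencing in 4 libraries, 2 from control and 2 from cKO animals. Total RNA was made into libraries with the NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq, per the labels' protocols, which leave open whether poly(A) selection or ribosomal RNA removal was used. The submitters' processing notes list fastp, HISAT2 and HTSeq and the mouse build GRCm38, with no role, order or version; how values per transcript were made and the annotation release are not given in the sources used here. The kit as named does not say whether strand was kept, so reads of a gene and of an antisense partner cannot be told apart.

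The authors deposited a table of 110295 transcripts with values to 2 decimals, whose header does not name the unit. The deposited values were taken as FPKM from the values themselves: value times transcript length, summed and divided by 1000, came to 1016302, 1019474, 1015550 and 1021998 in control 1, control 2, cKO 1 and cKO 2, while the plain column sums were 505075, 611466, 529298 and 631651. FPKM and RPKM cannot be told apart here. The control columns are named WT in the table although the labels give a heterozygous floxed genotype; columns were matched to libraries by group and replicate number. Low values of single-transcript genes between 300 and 1000 nt were whole multiples of the value of 1 read in 94.9%, 94.5%, 95.2% and 94.8% of cases, within a tolerance of 0.2 reads, which gave implied depths of 17369983, 23400913, 16894651 and 25690297 reads or fragments. Some genes used by every cell were listed at exactly 0, so a 0 is reported only as listed at 0. In 162 rows the symbol had been turned into a date by a spreadsheet, and all 162 were looked up by transcript ID. Lengths, coordinates and exons came from GENCODE M21 (GRCm38), which held 98.04% of the transcripts.

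FPKM were summed over the transcripts of a symbol (45803 symbols). Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested (13817) on log2(FPKM + 1), a scale that understates the change of low genes, with limma's moderated test with a mean-variance trend and genotype as the only term, and p was adjusted by Benjamini-Hochberg at 0.05. The design written before the data were examined assumed counts. Because the values were taken as FPKM, its stated fallback for normalized values was used for the main test. edgeR and DESeq2 were not run, and limma-voom on recovered reads served only as an alternative. There were 2 residual degrees of freedom. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, over lists with at least 5 measured members; 28 lists were adjusted together. The genes named were fixed by rule before the data were examined: Mettl14, Col17a1, Itga6 and Itgb4; the 8 genes with the largest rise and the 8 with the largest fall past the threshold, with non-overlapping libraries and a mean of at least 1 FPKM; for each list up to 4 members past the threshold or, if none passed, the 2 with the smallest p; and the 2 most abundant members of the marker, histone, mitochondrial, ribosomal and sex lists. The part of the rule on largest changes gave no gene. The values of 1 gene that the rule names are not reported here.

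Alternatives covered median-ratio scaling, equal column sums, a pseudocount of 0.1, other filters, limma-voom on recovered reads, the replicate number as a block, removal of length or GC trends, stricter thresholds and leaving out each library. After the exon trend was seen, each list was also set against 10000 random lists of other protein-coding genes matched on expression and on exon number or transcript length. Leaving out a library leaves 1 library in a group, which is then assumed to vary like the other group. The script was tested on simulated data built from the real means, the difference between replicate numbers and limma's fitted prior of the spread, with 200 of 13817 genes changed: without a block it called 0% at 2-fold and 57% at 4-fold with 0 unchanged genes called, and with the block 93.5% and 100% with 36 and 11 unchanged genes called. The simulation added a shift by replicate number and took its spread from the blocked fit. It therefore favours the block by construction and cannot show that blocking suits these libraries. Intervals and floors cover counting error only. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.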

Results

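RNA sequencing was carried out on epidermal keratinocytes, the main cell type of the outer skin layer, taken from newborn mice at postnatal day 0. The study compared conditional knockout animals (cKO), in which both alleles of Mettl14 were floxed and Cre recombinase was driven by the keratin 14 promoter, with control animals that carried the same Cre and only 1 floxed allele beside a wild-type allele. Mettl14 encodes a subunit of the enzyme complex that writes N6-methyladenosine (m6A) on RNA, and keratin 14 is made by basal keratinocytes. There were 2 control and 2 cKO libraries, each with a replicate number of 1 or 2 in the labels. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The values were deposited per transcript, were taken as FPKM and were summed here per gene symbol. The depth implied by the low values was 17369983 and 23400913 reads or fragments in control libraries 1 and 2, and 16894651 and 25690297 in cKO libraries 1 and 2. In the 4 libraries, 13837, 13534, 13450 and 13106 genes reached 1 FPKM in that order.

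The libraries differed more by replicate number than by genotype. The first principal component of the 500 most variable genes held 65.9% of the variance and placed the libraries numbered 1 (control -17.9, cKO -8.97) apart from those numbered 2 (control 7.88, cKO 18.9). The second component held 25.9% and separated cKO (11.99 and 4.82) from control (-5.78 and -11.0). Across genes, log2 values of control 1 correlated with those of cKO 1 at r = 0.977 and those of control 2 with cKO 2 at 0.976, against 0.966 between the control libraries and 0.956 between the cKO libraries; genes are not independent replicates. Mitochondrial transcripts took 4.08% of recovered reads in control 1 and 2.90% in cKO 1, against 1.62% and 1.14% in control 2 and cKO 2. Transcripts annotated as retained introns took 4.66% and 4.01% of the summed FPKM in the libraries numbered 1 and 2.83% and 2.28% in those numbered 2, control first. The RNA genes Rpph1 and Rmrp, components of RNase P and RNase MRP, took 1.24% and 2.05% of recovered reads in control 1 and cKO 1, and 3.57% and 3.51% in control 2 and cKO 2. For gene lists and for the genes of the study's title, values within each replicate number are therefore given beside the pooled ones.

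**Figure D1:**
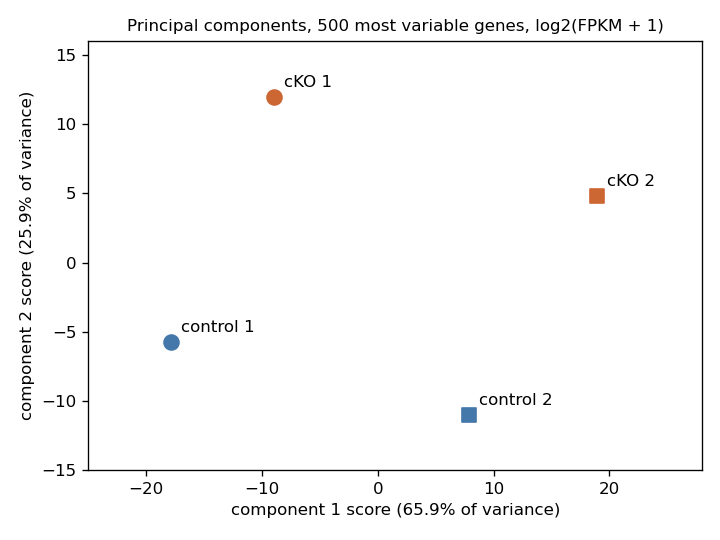
Scores of the 4 libraries on the first and second principal components of log2(FPKM + 1) over the 500 most variable genes, in arbitrary score units, with control libraries in blue, cKO libraries in orange, circles for replicate number 1 and squares for number 2. The horizontal axis (65.9% of the variance) separates the replicate numbers and the vertical axis (25.9%) separates the genotypes.

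The first question was whether the targeted gene and the genes named in the study's title differed between genotypes. Mettl14 (ENSMUSG00000028114, GRCm38 chromosome 3, 123368297 to 123386108) measured 6.70 ± 0.424 FPKM in control and 4.84 ± 1.49 in cKO (SD, n = 2 libraries each). Its log2 difference was -0.42 ± 0.26 (SE), with -0.21 within replicate number 1 and -0.63 within number 2. Residual Mettl14 RNA can come from the part of the gene outside the deletion, which the labels do not give, and the control animals carry only 1 intact allele in Cre-expressing cells. The most abundant transcript of Mettl14, with 11 exons, was listed at 4.82 and 5.15 FPKM in control libraries 1 and 2 and at 2.21 and 2.63 in cKO libraries 1 and 2. A transcript with 7 exons was listed at 1.22 and 0.89 in control and 1.27 and 0.41 in cKO, and 1 with 10 exons at 0.96 and 0.36 against 0.91 and 0.33, so these were nearly equal between the libraries numbered 1.

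Col17a1, Itga6 and Itgb4 encode collagen XVII and the integrin α6 and β4 chains, the transmembrane parts of the hemidesmosomes that fix basal keratinocytes to the basement membrane. Col17a1 (chromosome 19, 47646344 to 47692094) measured 65.9 and 123 FPKM in control libraries 1 and 2 and 43.5 and 86.0 in cKO libraries 1 and 2, a log2 difference of -0.55 ± 0.44 with -0.59 within number 1 and -0.51 within number 2. Itga6 (chromosome 2, 71745616 to 71858416) measured 73.6 and 81.9 in control and 61.5 and 71.3 in cKO, a difference of -0.23 ± 0.22 with -0.26 and -0.20 within the numbers. Itgb4 (chromosome 11, 115974709 to 116008412) measured 8.59 and 15.6 in control and 5.80 and 12.9 in cKO, a difference of -0.37 ± 0.43 with -0.50 and -0.25 within the numbers. Each of these genes and Mettl14 was lower in cKO than in the control library of the same number in 2 of 2 comparisons, and none passed limma's test (adjusted p = 0.959 for each). The size for Col17a1 rested on single libraries, at -0.996 without control replicate 1, -0.105 without control replicate 2, -0.067 without cKO replicate 1 and -1.035 without cKO replicate 2. Mettl14 lay at -0.684 without cKO replicate 1 and -0.159 without cKO replicate 2, and Itga6 at -0.15 without control replicate 2 and -0.121 without cKO replicate 1. For Itgb4 the difference turned to 0.02 without control replicate 2 and to 0.14 without cKO replicate 1, so its direction rests on these libraries.

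**Figure D2:**
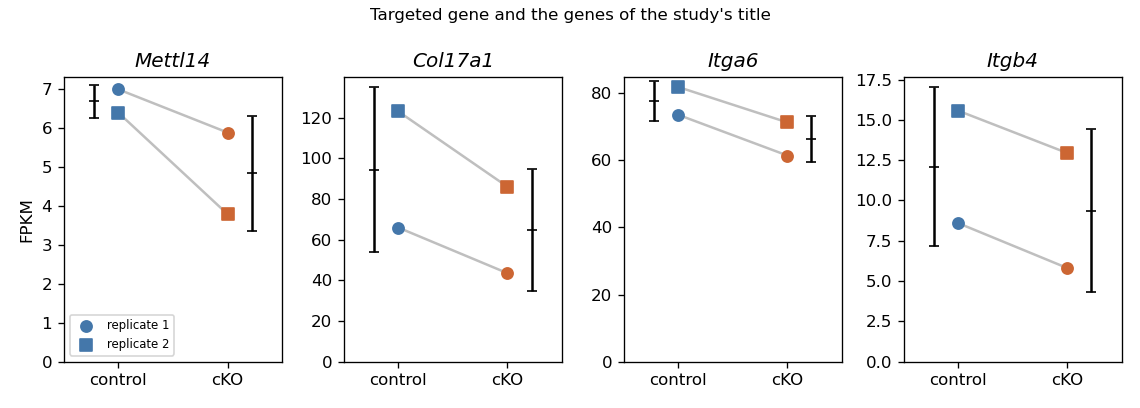
FPKM (vertical axes, from 0) of Mettl14, Col17a1, Itga6 and Itgb4 in control (blue) and cKO (orange) libraries, with circles for replicate number 1, squares for number 2, grey lines joining libraries that share a number, and black bars for the mean ± SD of the 2 libraries of a group. Each gene lies lower in cKO within both numbers, by log2 differences of -0.42, -0.55, -0.23 and -0.37 over both numbers, and the SD bars of the groups overlap for every gene shown.

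Over all genes, no difference between cKO and control passed the test without a replicate block. Of 13817 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.456 (Sowahc). At an unadjusted p under 0.05 there were 686 genes, 454 higher and 232 lower in cKO, against 691 expected by chance. limma-voom on recovered reads also called 0 genes. Both fits leave out the replicate number. With that number as a block, a pairing that the labels do not state, genes did pass, as the part on processing describes. Both cKO libraries lay outside the range of both control libraries for 32.8% of genes, and chance gives 33.3% for 2 against 2. These values for chance take the libraries as interchangeable, which their likeness by replicate number goes against. Matching them therefore does not show that no gene differs. The difference had the same sign within both replicate numbers for 9594 genes (69.4%). Differences within number 1 and within number 2 correlated across genes at r = 0.536. Both cKO libraries also lay toward number 2 on the first component, relative to the control of the same number. Since genes are not independent, this agreement does not tell a genotype effect from that shared shift. Genes at least 2-fold higher within both numbers came to 58 and genes at least 2-fold lower within both to 14. In simulated data with the spread of these libraries, the same test called 0% of genes changed 2-fold and 57% of genes changed 4-fold, of 200 changed genes of each size among 13817. When a single library was left out some genes passed. Such fits leave 1 library in a group with 1 residual degree of freedom and mix genotype with replicate number.

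The following genes were chosen after their values were seen, by the size of the difference among genes whose libraries did not overlap, and none passed the adjusted test with all 4 libraries. Sowahc measured 0.91 and 0.74 FPKM in control and 40.5 and 20.5 in cKO (log2 difference 4.03 ± 0.35). Fam46b measured 11.8 and 14.5 in control and 37.7 and 51.3 in cKO, and Mt4, a metallothionein of stratified epithelia, 13.4 and 33.0 against 61.9 and 103. Mrpl46 and Mrpl43, subunits of the mitochondrial ribosome, had log2 differences of 1.64 ± 0.25 and 1.58 ± 0.35, and Nxt1, a nuclear RNA export factor, 1.58 ± 0.27. S100a9 had a difference of 1.86 ± 0.52, and Ddit4l of 1.72 ± 0.46 (2.373 without cKO replicate 1 and 1.069 without cKO replicate 2). The small proline-rich genes Sprr2d, Sprr2a3, Sprr2g and Sprr2h, near-identical copies between which reads may be split, had differences of 2.02, 1.61, 1.59 and 1.55. Their size rested on the cKO libraries, at 3.119, 2.473, 2.111 and 2.273 without cKO replicate 1 and 0.919, 0.741, 1.076 and 0.825 without cKO replicate 2. Sprr2d lay at 2.46 without control replicate 2. Among lower genes, the T cell receptor segment Trdv4 measured 12.6 and 16.7 in control and 5.20 and 7.01 in cKO, and the natural killer receptor gene Klrd1 5.32 and 4.19 against 2.08 and 0.87. Tsc22d3, a glucocorticoid-induced gene, had a difference of -1.16 ± 0.41 (-1.746 without control replicate 1 and -0.568 without control replicate 2), Perm1 of -1.11 ± 0.32, Efcab1 of -1.09 ± 0.24, Fv1 of -1.05 ± 0.25 and Gucy1b3 of -1.03 ± 0.28. Rnu1b6, a multicopy U1 RNA gene whose reads are uncertain, measured 21.8 and 83.1 in control and 0 and 0.23 in cKO, where 0 means listed at 0. Fits without a library leave 1 library in a group and mix genotype with replicate number, so only sizes are given. Sowahc then lay between 3.558 and 4.509 and Rnu1b6 between -6.245 and -4.364. Fam46b lay between 1.457 and 1.893, Mt4 between 1.252 and 2.492, and Mrpl46 between 1.388 and 1.894. Mrpl43 lay between 1.193 and 1.976, Nxt1 between 1.317 and 1.85, S100a9 between 1.264 and 2.46, and Klrd1 between -1.615 and -0.895.

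Gene lists fixed before the data were examined were compared with limma's camera, which ranks a list against all other genes. Of 28 lists with at least 5 measured members, 12 passed at a preset correlation of 0.01, 7 higher and 5 lower in cKO. With the correlation estimated from the data 0 lists passed, and fry called 0. The test with an estimated correlation rests on 2 residual degrees of freedom, so it cannot tell whether correlation between genes undid a call. The m6A machinery list, with an estimated correlation of 0.005, below the preset, still went from a camera adjusted p of 0.0288 to 0.661. Most other called lists had higher estimates: 0.885 sebaceous, 0.735 hair shaft, 0.6 mitochondrial, 0.564 hemidesmosome, 0.419 G2/M and 0.329 leukocyte. The rest were 0.311 barrier lipid, 0.118 p53, 0.077 granular, 0.055 stress keratin and -0.044 melanocyte. Calls at the preset may be overstated for lists with high estimates, though each estimate is itself uncertain. The adjusted p with an estimated correlation is given for each list that passed at the preset. With all 4 libraries no member of any list passed over all genes tested, and the counts adjusted over the list alone were 0 unless given. Both cKO libraries lay toward number 2 on the first component. The median, number 2 minus number 1, had the call's sign for hair shaft (0.996), sebaceous (0.545), granular (0.296), p53 (0.244) and mitochondrial lists (-1.123). These calls were not separated from that axis. It opposed the call for leukocyte (0.452), hemidesmosome (0.437), G2/M (0.575) and barrier lipid (-0.306) lists. It was small for stress keratin (0.071), m6A (0.002) and melanocyte (-0.068) lists.

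The granular and cornified envelope list and the barrier lipid synthesis list were ranked higher in cKO at the preset correlation. The granular and cornified envelope list had 48 measured members and a median log2 difference of 0.48 (0.40 within number 1 and 0.35 within number 2), with 30 members higher within both numbers and 9 lower (camera adjusted p = 9.06e-05; adjusted p = 0.661 with an estimated correlation). Adjusted over the list alone, 2 members were higher: Tgm3, a transglutaminase that crosslinks the cornified envelope (49.9 and 47.9 FPKM in control, 112 and 123 in cKO), and Sprr1b, an envelope precursor (39.1 and 41.4 against 91.8 and 144). Other major members, chosen after their values were seen, were not higher by more than their error: Flg, Flg2 and Hrnr, of the filaggrin family, had differences of -0.40 ± 0.66, -0.43 ± 0.36 and -0.39 ± 0.29, and the envelope proteins Lor and Ivl of 0.10 ± 0.25 and -0.07 ± 0.51. The log2 difference of Sprr1b lay between 1.17 and 1.815 when a library was left out. The barrier lipid synthesis list (34 members) had a median of 0.19 (0.15 and 0.28), with 22 members higher within both numbers (camera adjusted p = 0.0123; adjusted p = 0.796 with an estimated correlation). Its examples were Degs1, the dihydroceramide desaturase (116 and 113 in control, 216 and 217 in cKO), and Abhd5, a lipase cofactor (51.3 and 65.0 against 84.8 and 90.4). The barrier call was lost without control replicate 2 (adjusted p = 0.91, opposite direction) and without cKO replicate 1 (0.788). The spinous list (17 members, median 0.12, with 0.17 and 0.12 within the numbers) did not pass (camera adjusted p = 0.0684). It was tested without its member Krt1, a spinous keratin gene that was listed at 0 in every library. Krt2 measured 0.86 and 0.52 in control and 2.42 and 4.03 in cKO, and Calm4 1737 and 2291 against 3015 and 3203. Without control replicate 1 and without cKO replicate 2 the spinous list passed (5.77e-04 and 0.00259), as it did with the length trend removed (0.0291) or with limma-voom (0.0318).

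Stress keratin and alarmin genes were ranked higher in cKO, with 19 measured members, a median of 0.46 (0.31 and 0.52), and 13 members higher within both numbers (camera adjusted p = 8.67e-07; adjusted p = 0.661 with an estimated correlation). Adjusted over the list alone, 2 members were higher: S100a8, a subunit of the alarmin calprotectin (5.92 and 6.51 FPKM in control, 15.1 and 24.0 in cKO), and Stfa2, a cysteine protease inhibitor (257 and 300 against 732 and 767). The log2 difference of S100a8 lay between 1.159 and 1.795 when a library was left out. The p53 target list (27 members) was also ranked higher, with a median of 0.23 (0.19 and 0.32) and 21 members higher within both numbers (camera adjusted p = 2.21e-04; adjusted p = 0.661 with an estimated correlation). Its examples were Aen, an apoptosis-enhancing nuclease (29.7 and 27.2 in control, 52.3 and 54.9 in cKO), and Tigar, a fructose bisphosphatase (3.47 and 3.91 against 6.44 and 7.32). The p53 call was lost without cKO replicate 2 (0.0873).

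The hemidesmosome and basement membrane list was ranked lower in cKO, more clearly within number 1. It had 25 measured members and a median of -0.32 (-0.50 within number 1 and -0.18 within number 2), with 18 members lower within both numbers and 1 higher (camera adjusted p = 9.06e-05; adjusted p = 0.785 with an estimated correlation). It includes Col17a1, Itga6 and Itgb4, which the study named, so it is not independent of the study's own choice. The main transcripts of its members have a median of 32 exons, and the 1439 protein-coding genes with over 20 exons had a median of -0.15 (-0.11 and -0.15 within the numbers). Among 10000 random lists of other genes matched on expression and exon number, a comparison added after the data were examined, the list's median lay at percentile 0.03 over both numbers and 0.00 within number 1, but at 35.2 within number 2, where matched lists had a mean of -0.16. The random lists draw genes independently, so these percentiles ignore correlation within the list and measure no spread between libraries. With the length trend removed the camera adjusted p was 0.00702. Dst, which encodes the hemidesmosome plaque protein BPAG1, measured 107 and 93.5 FPKM in control and 66.4 and 52.5 in cKO, and Col4a5, a type IV collagen chain, 15.1 and 18.1 against 10.2 and 11.2. The call was lost without control replicate 2 (0.0734) and without cKO replicate 1 (0.656). The list's median difference between replicate numbers, number 2 minus number 1, was 0.44. The basal keratinocyte list (16 members, median -0.23, with -0.43 and -0.02 within the numbers) did not pass (camera adjusted p = 0.458); Sfn measured 583 and 659 in control and 1047 and 1252 in cKO, and Trp63 99.6 and 109 against 76.3 and 76.8. Without control replicate 1 and without cKO replicate 2 it passed as lower (0.0255 and 0.00137). The hair follicle and epidermal stem cell list (14 members, median -0.13, with -0.17 and -0.07 within the numbers) did not pass (0.271), with Id2 at 23.3 and 32.2 in control and 15.3 and 23.2 in cKO and Id3 at 19.3 and 29.4 against 15.8 and 20.3. This list too passed as lower without control replicate 1 (0.0205) and without cKO replicate 2 (0.00506).

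Cell cycle lists moved apart between the replicate numbers. The G2/M list (30 members) was ranked lower, with a median of -0.32, but this was -0.63 within number 1 and 0.07 within number 2 (camera adjusted p = 2.92e-04; adjusted p = 0.785 with an estimated correlation), with 13 members lower within both numbers and 0 higher. The list's median was thus not lower within number 2, and without cKO replicate 1 the direction was opposite (0.57). Nusap1, a spindle protein, measured 21.5 and 20.4 FPKM in control and 8.86 and 14.4 in cKO, and Kif11, a mitotic kinesin, 24.6 and 18.7 against 13.9 and 13.02. The S phase list (32 members, median 0.01, with -0.23 and 0.26 within the numbers) did not pass (0.883); Pola1 measured 13.03 and 9.30 in control and 9.12 and 6.54 in cKO, and Ccne1 2.60 and 3.93 against 2.64 and 9.68. The replication-dependent histones (26 members, median 0.07, with -0.24 and 0.36 within the numbers) did not pass (0.576). Hist1h2ab and Hist1h2bc had differences of 0.64 ± 0.39 and 0.56 ± 0.41, and the abundant Hist1h4h and Hist1h4c of -0.07 ± 0.57 and 0.16 ± 0.64. Both lists followed the library left out. The S phase list passed as higher without cKO replicate 1 (3e-05) and as lower without cKO replicate 2 (9.51e-07). The histone list passed as higher without control replicate 2 (0.00224) and cKO replicate 1 (6.41e-05), and as lower without control replicate 1 (0.0172) and cKO replicate 2 (2.18e-06).

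The m6A machinery list (20 members) was ranked higher in cKO, with a median of 0.20 (0.19 and 0.18) and 11 members higher within both numbers and 4 lower (camera adjusted p = 0.0288; adjusted p = 0.661 with an estimated correlation). The list contains the targeted gene, and both methyltransferase subunits were among the 4 lower: Mettl14 at -0.42 and Mettl3 at -0.15 ± 0.25 (-0.16 and -0.15 within the numbers; 0.03 without control replicate 1 or without cKO replicate 2). Ythdf2, a reader protein that directs m6A-marked RNA to decay, measured 33.6 and 37.1 FPKM in control and 58.0 and 73.8 in cKO, and Rbm15, an adaptor of the writer complex, 13.8 and 11.6 against 17.4 and 16.9. The call was lost without control replicate 1 (0.0819), control replicate 2 (0.187) or cKO replicate 1 (0.57).

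Appendage lists gave calls that depended on single libraries. The hair shaft and inner root sheath list (28 members, median 0.29, with 0.27 and 0.30 within the numbers) was ranked higher (camera adjusted p = 0.0288; adjusted p = 0.796 with an estimated correlation) and was ranked lower without control replicate 1 (0.0306) and without cKO replicate 2 (0.0196). Its members S100a3 and Krt32 had differences of 0.88 ± 0.53 and 0.31 ± 0.20; that of S100a3 was 0.302 without control replicate 1, 1.449 without control replicate 2, 1.496 without cKO replicate 1 and 0.255 without cKO replicate 2. The sebaceous gland list (14 members, median 0.19, with 0.10 and 0.28 within the numbers) was ranked higher (camera adjusted p = 0.0409; adjusted p = 0.796 with an estimated correlation), a call lost without control replicate 1 (0.898) and without cKO replicate 2 (0.519, opposite direction). Dgat2l6 and Awat1, acyltransferases of the gland, had differences of 0.62 ± 0.24 and 0.42 ± 0.29. The list of hair follicle morphogenesis regulators (27 members, median -0.12, with -0.23 and 0.01 within the numbers) did not pass (0.899), with Eda2r at 0.80 ± 0.27 and Cux1 at -0.49 ± 0.31; it passed as lower without control replicate 1 (0.0238) and cKO replicate 2 (7.73e-04), and as higher without cKO replicate 1 (0.0329). With the GC trend of each library removed, the hair shaft (0.0792) and sebaceous (0.0555) calls were lost, as was the sebaceous call with limma-voom (0.0613).

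Markers of other cell types were compared because a keratinocyte preparation can hold them. The leukocyte list (24 measured members) was ranked lower in cKO, with a median of -0.48 (-0.59 within number 1 and -0.35 within number 2) and 21 members lower within both numbers (camera adjusted p = 4.38e-07; adjusted p = 0.661 with an estimated correlation). Cd3g and Cd3d, chains of the T cell receptor complex, measured 39.0 and 37.8 and 10.1 and 12.1 FPKM in control, and 18.3 and 21.04 and 6.17 and 5.44 in cKO. The antigen presentation genes Cd74 and H2-Aa had differences of -0.60 ± 0.36 and -0.57 ± 0.28, which were -0.213 and -0.296 without cKO replicate 1 and -0.99 and -0.835 without cKO replicate 2. The melanocyte list (11 members, median -0.35, with -0.32 and -0.27 within the numbers) was ranked lower (camera adjusted p = 0.0186; adjusted p = 0.661 with an estimated correlation), with Kit at -0.60 ± 0.21, Gpnmb at -0.41 ± 0.19, Dct at -0.35 ± 0.26 and Pmel at -0.11 ± 0.26. That call was lost without control replicate 1 (0.271), cKO replicate 1 (0.0733) or cKO replicate 2 (0.158).

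The dermal fibroblast list (17 members, median -0.07, with -0.37 and 0.05 within the numbers) did not pass (camera adjusted p = 0.151), although its abundant members Vim and Postn had differences of -0.62 ± 0.26 and -0.74 ± 0.34 and Dcn of -0.72 ± 0.23; Postn lay at -1.139 without cKO replicate 1 and -0.334 without cKO replicate 2. The Schwann cell and nerve list (5 members, median -0.35, with -0.32 and -0.38 within the numbers) did not pass (0.0565), with Egfl8 at -0.74 ± 0.28, Sox10 at -0.35 ± 0.20 and Mbp at 0.20 ± 0.29. The Merkel cell list (6 members, median -0.10, with 0.01 and -0.08 within the numbers) did not pass (0.58), with Krt8 at -0.29 ± 0.26, Isl1 at -0.30 ± 0.28 and Krt18 at 0.21 ± 0.24. Erythroid genes varied by library rather than by genotype (6 members, 1.77 within number 1 and -0.96 within number 2, camera adjusted p = 0.161). Hbb-bs measured 180 and 459 FPKM in control and 688 and 222 in cKO, Hba-a1 103 and 265 against 371 and 121, and Alas2 2.64 and 8.48 against 10.9 and 4.56. The endothelial, skeletal muscle and adipocyte lists had 2, 3 and 3 measured members and no test; Ramp2 and Egfl7 had differences of 0.61 ± 0.28 and 0.48 ± 0.35, Acta1, Tnni2 and Mylpf of -0.14 ± 0.45, 0.06 ± 0.28 and 0.01 ± 0.23, and Retn, Lpl and Fabp4 of -0.39 ± 0.29, 0.08 ± 0.30 and 0.04 ± 0.38. Single libraries changed 3 of these outcomes: the fibroblast list passed as lower without cKO replicate 2 (0.0196), the Schwann list as lower without control replicate 1 (0.0363), and the erythroid list as higher without control replicate 2 (8.43e-06) or cKO replicate 2 (3.3e-07). The Schwann list also passed with the length (0.0453) or GC trend (0.0473) removed.

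**Figure D3:**
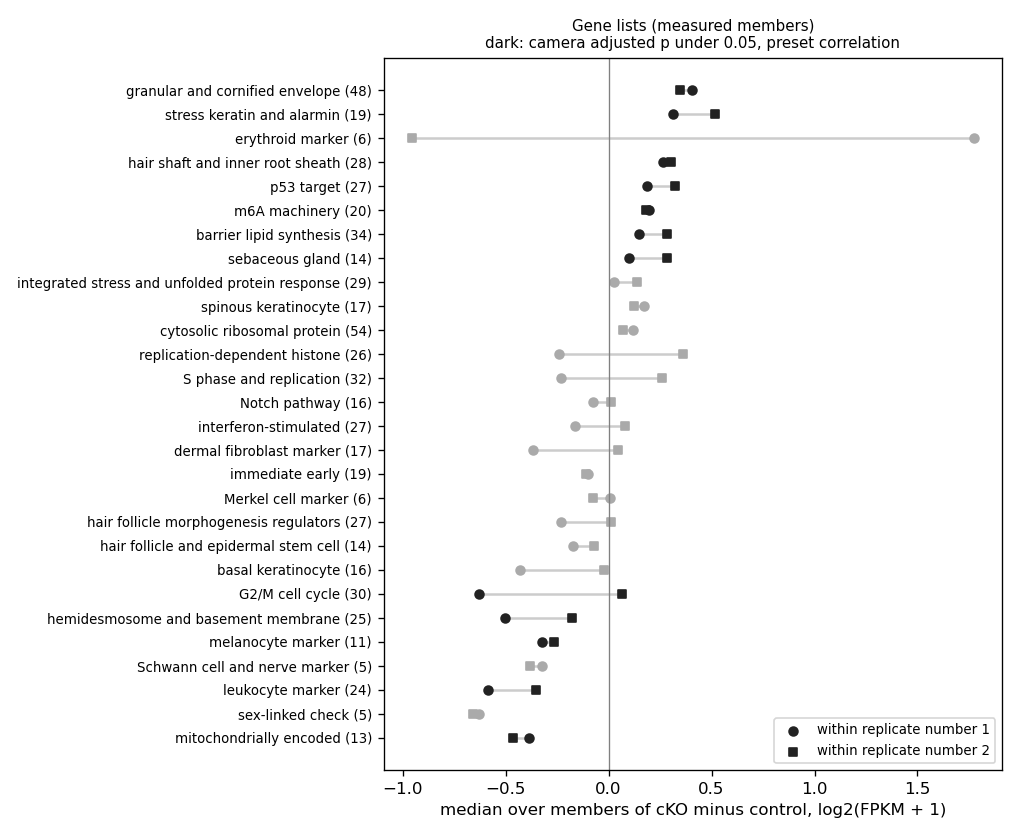
Median over the measured members of each of 28 gene lists (vertical axis, member counts in brackets) of the difference cKO minus control in log2(FPKM + 1) (horizontal axis), within replicate number 1 (circles) and number 2 (squares), with dark points for lists with a camera adjusted p under 0.05 at the preset correlation and grey points for the others. The leukocyte list lies at -0.59 and -0.35 and the granular and cornified envelope list at 0.40 and 0.35, while the G2/M list lies at -0.63 and 0.07.

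Mitochondrially encoded mRNAs (13 members) were ranked lower in cKO, with a median of -0.66 (-0.39 and -0.47 within the numbers) and 8 members lower within both numbers (camera adjusted p = 0.00157; adjusted p = 0.785 with an estimated correlation). The call was lost without control replicate 1 (0.13) and with the GC trend of each library removed (0.0518). Adjusted over the list alone, 2 members were lower: mt-Nd3 measured 3300 and 2108 FPKM in control and 277 and 559 in cKO, and mt-Nd4l 99.4 and 56.4 against 7.57 and 13.5. The abundant mt-Co1 and mt-Nd1 had differences of -0.24 ± 0.96 and -0.01 ± 0.77, and the short mt-Atp8 of -2.13 ± 1.10. The mt-Atp8 difference rests on control replicate 1, at 91.7 FPKM against 6.28, 5.51 and 4.39 in control 2, cKO 1 and cKO 2. It was -0.297 without control replicate 1 and -3.968 without control replicate 2. With a library left out, the log2 difference of mt-Nd3 lay between -3.248 and -2.237 and that of mt-Nd4l between -3.172 and -2.365. Cytosolic ribosomal protein genes (54 members, median 0.09, with 0.12 and 0.07 within the numbers) did not pass (0.303); Rpl7a measured 340 and 292 in control and 115 and 285 in cKO, and Rps28, Rps18 and Rps14 had differences of 0.41 ± 0.41, -0.03 ± 0.55 and 0.09 ± 0.57. The ribosomal list passed as higher without control replicate 2 (0.00395).

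The remaining lists did not pass. The interferon-stimulated list (27 members, median -0.02, with -0.16 and 0.08 within the numbers, camera adjusted p = 0.801) held Ifi27 at -0.63 ± 0.20 and Isg15 at 0.61 ± 0.29. The integrated stress and unfolded protein response list (29 members, median 0.14, with 0.03 and 0.14 within the numbers, 0.216) held Chac1 at 0.53 ± 0.24 and Pdia4 at 0.50 ± 0.22. The immediate early list (19 members, median -0.07, with -0.10 and -0.11, 0.565) held Jund at 0.48 ± 0.21 and Fos at -0.76 ± 0.36, and the Notch pathway list (16 members, median 0.00, with -0.07 and 0.01, 0.883) held Heyl at 0.41 ± 0.25 and Lfng at -0.39 ± 0.40. For the Notch list the median and mean were slightly below 0 and the camera direction was upward. The sex-linked list (5 members, median -0.56, with -0.63 and -0.66 within the numbers, 0.0912) did not pass; the X-inactivation RNA Xist measured 89.0 and 90.7 FPKM in control and 84.7 and 54.4 in cKO, and the Y-linked Eif2s3y 32.7 and 10.5 against 16.3 and 5.02, so RNA of both kinds was present in every library. Eif2s3y varied between replicate numbers as well as genotypes. More female cells in cKO would lower Y-linked RNA and raise Xist, yet all 5 tested members were lower within both numbers. These values argue against an unequal mix of the sexes as the whole genotype difference and leave it open as a part. A list joining Xist with Y-linked genes cannot test such a mix, since its members would move apart. The log2 difference of Eif2s3y was -1.726 without control replicate 2 and -0.171 without control replicate 1. The sex-linked list passed as lower without control replicate 2 (8.9e-10) and without cKO replicate 1 (1.47e-05).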

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

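The single result listed here was picked from transcript values that the comparison of genes does not use separately, after the values were seen. A short transcript of Mettl14 (ENSMUST00000174006, 634 nt, 4 exons, GRCm38 chromosome 3, 123369472 to 123374831) was listed at 0 in both control libraries and at 1.5 FPKM in cKO 1 and 0.32 FPKM in cKO 2, a signal absent from the controls' values. These values equal about 16.1 and 5.2 recovered reads, above the 3 reads that a count of 0 allows. Its annotated exons skip exon 8 of the 11-exon transcript (chromosome 3, 123373970 to 123374062), while that transcript was listed at 4.82 and 5.15 FPKM in control and 2.21 and 2.63 in cKO. Over the 108134 transcripts with a length, 459 were listed at 0 in both control libraries and above 3 reads in both cKO libraries, and 486 showed the opposite. The pattern was thus seen in a small share of transcripts, but about as often in either direction. How reads were divided among overlapping transcripts is not given in the sources used here, and no explanation was tested.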

How the results depend on the processing

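The rescaling to equal column sums, the removal of GC trends, the block with limma-voom, the length trends beyond the count of genes, and the filter, pseudocount and limma-voom settings for gene lists were chosen after seeing the data. The planned edgeR and DESeq2 settings were not run, because the values are not counts, and total-count scaling is what FPKM already holds. The count of 0 genes was also found with median-ratio scaling, equal column sums, a pseudocount of 0.1, no filter, a filter on recovered CPM, limma-voom, and the length or GC trend removed. The count stayed 0 with a fold change of at least 2, an adjusted p under 0.01 or limma's treat, as it had to once no gene passed. It rose to between 9 and 71 when a library was left out (14 without control replicate 1, 37 without control replicate 2, 71 without cKO replicate 1, 9 without cKO replicate 2); these fits have 1 residual degree of freedom. In simulated data the test without the block called no 2-fold change, and with the block it called 93.5% of them beside 36 unchanged genes. The blocked fit was right by construction there, because the simulation included a shift by replicate number.

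The libraries share only a replicate number. Deviations from the group means correlated at 0.722 within each number across genes, a value that groups of 2 force to be equal for both numbers. With the replicate block the count rose to 900 (626 higher, 274 lower), to 655 with the length trend removed as well, to 1142 with the GC trend removed as well and to 1302 with limma-voom on recovered reads and the block. In simulated data of 13817 genes the blocked fit also called 36 unchanged genes beside 187 of 200 changed 2-fold. The 36 were part of 223 calls, a larger share than the threshold of 0.05 allows, although the simulation favours the block. With the block, Col17a1 passed at -0.551 (adjusted p = 0.0243; -0.634 with the GC trend removed, -0.549 with limma-voom), and Mettl14 passed with limma-voom and the block alone (-0.646, adjusted p = 0.0459); the adjusted p of Itga6 and Itgb4 stayed above 0.05 in all these fits. Of the genes named by the rule 35 of 82 passed with the block, and of those chosen by size 21 of 22. Those of the 35 with an adjusted p under 0.01 were Stfa2 (0.00147), Tgm3 (0.0024), Sprr1b (0.00317), mt-Nd4l (0.00377), S100a8 (0.00442), mt-Nd3 (0.0047), Degs1 (0.0048), Aen, Cd3g and Ythdf2 (0.00648 each), S100a3 (0.0071), Eif2s3y (0.00739), Sfn (0.00876) and Dst (0.00884). The block with camera passed 15 lists, adding spinous (0.00875), ribosomal (0.0233) and sex-linked (0.000534). With the length trend removed as well it passed 14, adding spinous (0.00338) and sex-linked (0.00151), and with the GC trend removed as well 16, adding spinous (0.0218), sex-linked (0.00851), fibroblast and Schwann. With limma-voom and the block 14 passed, adding spinous (0.00792), ribosomal (0.0151) and sex-linked (0.000116) and losing m6A machinery (0.0517).

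Of 28 lists, 12 passed, 0 with camera's estimated correlation, 0 with fry, 11 to 17 without a library, 14 with the length trend removed (adding spinous and Schwann), 10 with the GC trend removed (losing hair shaft, sebaceous and mitochondrial, adding Schwann), 12 with limma-voom (adding spinous, losing sebaceous) and 12 with the scaling, pseudocount and filter settings. Lists matched on expression and exon number were added after the data were examined. Against them the medians of the 12 lay at percentile 0.87 or lower, or 98.46 or higher, in the list's direction within both numbers. Exceptions were hemidesmosome (35.2 within number 2), G2/M (93.7 within number 2), m6A machinery (96.4 within number 2) and sebaceous (81.5 within number 1). The random lists draw genes independently, so these percentiles ignore correlation within a list and measure no spread between libraries. When a library was left out, the sign of the log2 difference changed for these genes, whose range is given: Acta1 (-0.749 to 0.468), Alas2 (-0.223 to 1.158), Ccne1 (-0.211 to 1.342), Col3a1 (-0.244 to 0.309), Fabp4 (-0.332 to 0.409), Fbln1 (-0.047 to 0.753), Flg (-0.805 to 0.002), Hba-a1 (-0.441 to 1.164), Hbb-bs (-0.371 to 1.257), Hist1h4c (-0.588 to 0.906), Hist1h4h (-0.6 to 0.464), Itgb4 (-0.89 to 0.145), Ivl (-0.691 to 0.544), Lfng (-0.939 to 0.161), Lor (-0.078 to 0.272), Lpl (-0.16 to 0.328), Mbp (-0.097 to 0.502), Mettl3 (-0.337 to 0.033), Mylpf (-0.071 to 0.101), Pmel (-0.27 to 0.049), Rps14 (-0.289 to 0.462), Rps18 (-0.31 to 0.261), Rps28 (-0.004 to 0.821), Tnni2 (-0.227 to 0.341), mt-Atp6 (-4.294 to 0.279), mt-Co1 (-0.906 to 0.428), mt-Co2 (-4.095 to 0.356), mt-Co3 (-3.801 to 0.418) and mt-Nd1 (-0.721 to 0.702). The size moved by over 1.5 times with no change of sign for 36 of the 115 genes followed: Awat1 (0.121 to 0.728), Cd74 (-0.99 to -0.213), Col17a1 (-1.035 to -0.067), Cux1 (-0.879 to -0.11), Dct (-0.489 to -0.208), Ddit4l (1.069 to 2.373), Egfl7 (0.121 to 0.843), Eif2s3y (-1.726 to -0.171), Flg2 (-0.78 to -0.082), Fos (-1.274 to -0.246), H2-Aa (-0.835 to -0.296), Heyl (0.242 to 0.585), Hist1h2ab (0.213 to 1.067), Hist1h2bc (0.141 to 0.978), Hrnr (-0.694 to -0.088), Id2 (-0.798 to -0.23), Id3 (-0.687 to -0.105), Isg15 (0.3 to 0.925), Isl1 (-0.544 to -0.066), Itga6 (-0.332 to -0.121), Krt18 (0.121 to 0.29), Krt8 (-0.512 to -0.07), Mettl14 (-0.684 to -0.159), Nusap1 (-1.154 to -0.511), Pola1 (-0.684 to -0.238), Postn (-1.139 to -0.334), Ramp2 (0.362 to 0.86), Retn (-0.675 to -0.105), Rpl7a (-1.448 to -0.145), S100a3 (0.255 to 1.496), Sprr2a3 (0.741 to 2.473), Sprr2d (0.919 to 3.119), Sprr2h (0.825 to 2.273), Tsc22d3 (-1.746 to -0.568), Xist (-0.713 to -0.085) and mt-Atp8 (-3.968 to -0.297). The camera direction changed for these lists, with the range of the adjusted p: G2/M cell cycle (2.53e-19 to 0.57), Merkel cell marker (0.315 to 0.97), Notch pathway (0.23 to 0.866), S phase and replication (9.51e-07 to 0.223), barrier lipid synthesis (9.89e-07 to 0.91), basal keratinocyte (0.00137 to 0.786), cytosolic ribosomal protein (0.00395 to 0.284), erythroid marker (3.3e-07 to 0.442), hair follicle and epidermal stem cell (0.00506 to 0.91), hair follicle morphogenesis regulators (0.000773 to 0.156), hair shaft and inner root sheath (4.87e-13 to 0.0306), interferon-stimulated (0.169 to 0.891), replication-dependent histone (2.18e-06 to 0.0172), sebaceous gland (0.000442 to 0.898) and sex-linked check (8.9e-10 to 0.615). Other settings turned the sign of the following genes, and their values with the length or GC trend removed were equal with and without the block. Tnni2 went to -0.048 (length) and -0.014 (GC), Mylpf to -0.028 (equal column sums), -0.09 (length) and -0.023 (GC), Lpl to -0.2 (limma-voom) and -0.162 (limma-voom with block), Fabp4 to -0.033 (length), Col3a1 to -0.024 (equal column sums) and -0.003 (GC), Lor to -0.174 (GC), Rps14 to -0.03 (length), and mt-Nd1 to 0.239 (GC) and 0.012 (limma-voom). Lists whose camera direction turned, none of them past the threshold, were hair follicle morphogenesis (adjusted p = 0.866 with the CPM filter, 0.94 with length, 0.925 with limma-voom), S phase (0.994, equal column sums), interferon (1, no filter), Notch (0.747 with GC, 0.541 with GC and block, 0.993 with fry), histones (0.94 with length, 0.936 with length and block, 0.966 with GC) and ribosomal proteins (0.942, length). The cause of these changes was not tested.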

Other observations

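All tests in this part were chosen after the results they concern were seen. Grouped by the exon number of each gene's most abundant transcript, protein-coding genes with few exons lay higher in cKO and genes with many exons lower. The median log2 difference was 0.09 for 367 genes with 1 exon, 0.20 for 612 with 2, 0.12 for 738 with 3, 0.08 for 1809 with 4 to 5, 0.02 for 2290 with 6 to 8, -0.03 for 2251 with 9 to 12, -0.08 for 2240 with 13 to 20 and -0.15 for 1439 with over 20. The medians for 2 exons were 0.18 within number 1 and 0.22 within number 2, and those for over 20 exons -0.11 and -0.15. The exon groups also differed between replicate numbers, from 0.30 for 1 exon to -0.07 for over 20 (number 2 minus number 1).

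The 1717 genes with 1 to 3 exons had a median of 0.15 (0.13 within number 1 and 0.19 within number 2). Against 10000 random lists of genes with at least 4 exons, matched on expression and in turn on transcript length, GC content and the difference between replicate numbers, the median was higher by at least 0.141, 0.171 and 0.175 within either number and above every matched list, which argues against each of these as the whole cause; matching on all of them together left 0.145. A candidate explanation is loss of m6A, which no value here measures directly. The GGACT-rich 33.3% of these genes, GGACT being a core m6A motif, lay above lists of the others matched on expression, GC content, length and number difference by 0.032 within number 1 (percentile 98.5) and 0.065 within number 2 (0.044 and 0.077 with GC content alone matched), which is in line with it but small. Matched lists draw genes independently, so these comparisons ignore correlation between genes and measure no spread between libraries. A difference in RNA quality or in unspliced RNA between the genotypes stays open, since retained-intron shares were lower in cKO within both numbers.

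The 24 leukocyte markers had a median of -0.48 in cKO. The difference that separates the replicate numbers would raise them in cKO, since their median was higher in number 2 by 0.452 (percentile 99.99 of matched lists) and cKO libraries lie toward number 2, which argues against it as the whole cause. A lower share of every other cell type stays open: the 37 markers of fibroblasts, melanocytes, Merkel and Schwann cells had a median of -0.184, and 26 of them were below 0, with the melanocyte and Schwann lists at -0.35 each and the abundant Vim, Postn and Dcn at -0.62, -0.74 (-0.334 without cKO replicate 2, -1.139 without cKO replicate 1) and -0.72, although Fbln1 lay at 0.35 (-0.047 without cKO replicate 2) and Col3a1 at 0.03 (-0.244 without control replicate 2, -0.013 without cKO replicate 1). Over all these markers 0.12% and 1.54% of random relabellings gave as large a gap within numbers 1 and 2, but within number 2 this was 5.89%, 3.73% and 10.88% among markers with a mean of at least 5, 10 and 20 FPKM; genes are not independent. Fewer leukocytes, or less RNA from them, in the cKO epidermis may account for it too, which stays a hypothesis, and unequal recovery of cells was not tested.

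The neighbouring mitochondrial genes mt-Nd3 and mt-Nd4l had log2 differences of -2.74 and -2.77 (-3.57 and -3.55 within number 1, -1.91 and -1.99 within number 2). The other 11 mitochondrially encoded mRNAs had a median of -0.281 and fell into groups: mt-Atp8, mt-Atp6, mt-Co2 and mt-Co3 lay at -2.13, -2.01, -1.87 and -1.69, and the other 7 between -0.655 and -0.009. Within number 1 the first group lay at -3.83, -3.55, -3.54 and -3.17, against -3.57 for mt-Nd3, but within number 2 at -0.43, -0.47, -0.19 and -0.21, and without control replicate 1 at -0.297, 0.279, 0.356 and 0.418. Since mt-Co1, mt-Nd1 and mt-Cytb lay at 0.03, 0.26 and 0.10 within number 1, the values argue against an equal loss of all mitochondrial RNA as the whole cause and leave a loss open as a part, and 176 other genes under 400 nt, with a median of 0.052, argue against a loss shared by all short transcripts. How reads of adjoining genes were assigned, and what sets control 1 apart, could not be examined and stays open, and no biological explanation was tested.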
